A study of Mus musculus with 4 samples.

How the data were processed

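RNA from mouse T cell cultures, taken at day 2, was measured on 4 Affymetrix arrays. There were 2 control arrays and 2 arrays for 0.1 mM butyrate, and group and replicate number came from the sample titles. The deposited values are normalized log2 signals per probe set, with 1 column per array. The log2 scale was read from the values themselves, and the background correction, summary and normalization behind them are not given in the sources used here. The genome build was mm9, per the submitters' processing notes. Per the labels' protocols, samples were fragmented with an enzyme and labelled with biotin. Sorted values of the arrays differed by at most 0.155, so the arrays held nearly the same distribution of values, by a step that the sources used here do not give. That limits how far a shift of most transcripts in one direction could be seen. No columns of other samples were present. Array medians were 6.83 and 6.73 in controls and 6.79 and 6.81 with butyrate.

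Probe sets were named from the platform annotation, which can be old. Of 35557 probe sets, 23410 were listed there, 21789 with 1 symbol and 1621 with several. The other 12147 were unnamed here. Entrez identifiers of 21698 were found in a RefSeq gene table of another assembly, GRCm38.p6, which was used for names only, so no coordinates are given. For each of 19938 genes the probe set with the highest mean over the arrays was tested. Of 999 genes with several probe sets, 2 had probe sets called in both directions. Probe sets with several symbols were left out of the comparison, and Cdkn1a and H1f0 were not analysed here for lack of a probe set that names them alone.

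Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, prior degrees of freedom 5.92), two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The fit has no block. The 4 arrays allow a median SE of 0.065, and the smallest called change was 0.21. Gene lists were tested against all other genes with camera at a preset correlation of 0.01, and again with an estimated correlation. The second form takes its degrees of freedom from the 4 arrays rather than from the genes, which leaves it little power. The rotation test fry asked a different question, whether a list's genes move one way on balance, without comparing them with other genes. A list needed at least 5 measured members, which 35 of 36 lists had. Figures were drawn with matplotlib 3.10.9.

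The comparison, the lists, the naming rule and the alternatives were fixed before the data were examined, except where said. Genes were named by 3 rules. The first took the 12 largest rises and 12 largest falls among called genes with a descriptive symbol, no overlap between the arrays of the groups, and a higher group mean above the median probe set, 6.79. The second took up to 4 members of each list with the smallest p. The third was a set of lineage, receptor and cell cycle genes, of which 16 were measured and 1 is not reported here. Together they named 159 genes. Called members of lists with few calls, and some that ran against the direction of their list, were also named, after their values were seen.

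Alternatives were a replicate block, quantile normalization, arrays centred on their median, and filters at the median and the 33rd percentile of signal. Others were a variance trend, a robust prior, the mean of all probe sets of a gene, all probe sets tested by themselves, an offset of 16 on the linear scale, a fold change of at least 1.5, an adjusted p under 0.10, and each array left out in turn. A fit without 1 array takes the lone array of its group to vary like the other pair. Cyclic loess normalization was added after seeing the data. The tests were tested on simulated data with 200 of 19938 genes changed, over 10 runs of the comparison of butyrate with control. Limma recovered 0.8% of genes changed by 0.3 on the log2 scale, 41.2% at 0.5, 83.6% at 1 and 96.4% at 2, and 1% of calls were false. The data held many more changes (13.3% of genes called), which loosens the adjusted threshold, so these recoveries do not carry over to the data. Camera called 100% of 50 simulated lists of 30 genes moved by 0.3 and 4% of unchanged lists at p under 0.05. Simulated noise was drawn for each gene separately, so this does not cover lists of correlated genes.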

Results

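Naive CD4+ T cells from the spleens of C57BL/6 mice were cultured with interleukin-2 and TGF-beta, which induce regulatory T (Treg) cells, and received either vehicle or 0.1 mM butyrate. Butyrate is a short-chain fatty acid that inhibits histone deacetylases. RNA taken at day 2 was measured on 4 Affymetrix arrays, 2 for control and 2 for butyrate. Each array gave a normalized log2 signal for 35557 probe sets, from which 19938 genes were tested. The comparison asks which transcripts differ when butyrate is added to a Treg-inducing culture. Median signals of the arrays ran from 6.73 to 6.83. Differences between replicate arrays had an SD across genes of 0.129 in controls and 0.105 with butyrate, against 0.217 to 0.238 between arrays of different groups. Pearson's r across probe sets, which are not independent replicates, was 0.9945 between controls and 0.9974 between butyrate arrays, against 0.9934 to 0.9948 across groups, so by r the control pair did not stand apart. The labels do not say whether the 2 arrays of a group came from separate cultures or animals, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision. Changes below are log2 differences, butyrate minus control, with the SE of the limma fit after the ± sign (2 arrays against 2) and p-values adjusted by the Benjamini-Hochberg method. Members of a list given without an SE, outside the 12 largest rises and falls, were mostly named after their values were seen. They mostly came from lists with few called members or ran against the direction of most called members.

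Butyrate raised 1371 genes and lowered 1287, which together were 13.3% of the genes tested. Among genes with a descriptive symbol and a signal above the median probe set, the largest rises were in Cxcr5, the receptor for the chemokine CXCL13 (1.95 ± 0.088), and H2-Ob, a chain of the class II-related H2-O molecule (1.92 ± 0.094). Gadd45g, a stress-response gene (1.89 ± 0.063), Lrrc6 (1.89 ± 0.097), Vat1 (1.79 ± 0.087) and Gimap7, a GTPase of lymphocytes (1.72 ± 0.099), followed. Il7r, the interleukin-7 receptor alpha chain (1.55 ± 0.108), Plaur, the urokinase receptor (1.55 ± 0.069), and Lif, the cytokine leukaemia inhibitory factor (1.43 ± 0.074), were also among the top 12, with Tm6sf1 (1.47), Mirt1 (1.44) and the protease gene Lgmn (1.44). The 12 largest falls exceeded the 12 largest rises in size. Il1a, which encodes interleukin-1 alpha, went from a signal of 9.97 ± 0.088 (SD, n = 2) to 7.22 ± 0.226 (SD, n = 2), a change of -2.76 ± 0.104 or 6.76-fold. Spin4 (-2.53 ± 0.095), Igfbp7 (-2.41 ± 0.083), Idi2 (-2.40 ± 0.062), Plek (-2.31 ± 0.069) and Tnfsf4, the OX40 ligand (-2.20 ± 0.063), followed. Next came Cth, an enzyme that makes cysteine (-2.17), the amino acid transporter Slc7a3 (-2.14), the transcription factor Npas4 (-2.04), the opioid precursor gene Penk (-2.02), the chemokine gene Xcl1 (-1.83) and the cystine transporter Slc7a11 (-1.83). All 24 of these genes kept their calls when any 1 array was left out. Most changes were small, with a median size of 0.36 among called genes, and 98 genes changed at least 2-fold (52 higher and 46 lower). The count of called genes was 1323 without butyrate replicate 1 and 1197 without butyrate replicate 2, and 437 with a fold change of at least 1.5. Testing each of the 35557 probe sets by itself gave 214, and quantile normalization left 799 lowered genes.

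**Figure D1:**
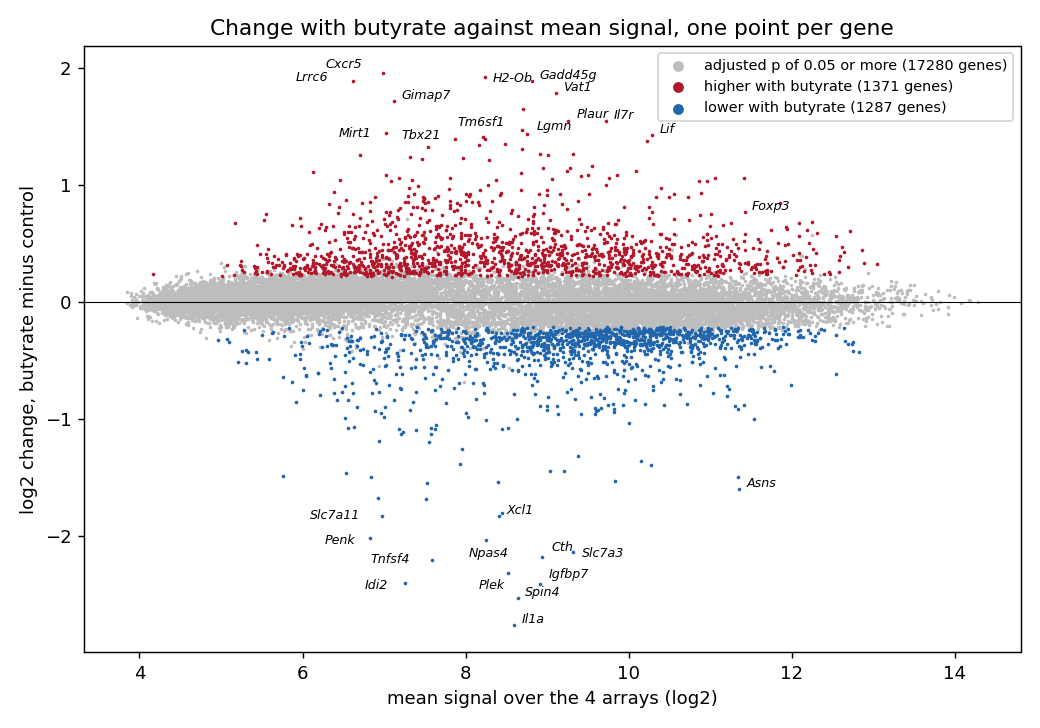
Each point is a gene, placed by its mean log2 signal over the 4 arrays (horizontal axis) and its log2 change, butyrate minus control (vertical axis), with 1371 raised genes in red, 1287 lowered genes in blue and the others in grey. The 24 genes of largest change and Foxp3, Tbx21 and Asns are named, and the lowest point is Il1a at -2.76.

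Foxp3, which encodes the transcription factor that defines Treg cells, rose. Its signal was 11.04 ± 0.123 (SD, n = 2) in controls and 11.81 ± 0.054 (SD, n = 2) with butyrate, a change of 0.77 ± 0.075 or 1.70-fold (adjusted p = 0.000638). Other Treg genes split. Among the 38 measured members of the Treg list, 14 rose and 6 fell (15 and 7 adjusted over the list alone), and 11 and 4 of these kept their calls when any 1 array was left out. Il10ra, a chain of the interleukin-10 receptor (1.41 ± 0.065), and Gpr83, a receptor gene of Treg cells (0.90 ± 0.073), rose with Foxp3. Penk (-2.02 ± 0.078), Nrp1, the neuropilin-1 gene (-0.96 ± 0.060), and Ikzf2, which encodes Helios (-0.46 ± 0.060), fell. Il2ra, the interleukin-2 receptor alpha chain, differed by 0.09 ± 0.060 (adjusted p = 0.388) and Il10 by 0.07 ± 0.068 (adjusted p = 0.587), and neither passed. Il10 was dim, at 5.3 in controls and 5.4 with butyrate, below the 33rd percentile of probe sets (5.82), so a change could be missed. Ctla4, an inhibitory receptor gene, was higher by 0.24 ± 0.061 (adjusted p = 0.0366). It did not pass without control replicate 2 (adjusted p = 0.107), butyrate replicate 1 (0.115) or butyrate replicate 2 (0.196), nor with arrays centred on their median (0.163), among alternatives with adjusted p from 0.0102 to 0.196. The list as a whole was higher than other genes (camera, median 0.10, adjusted p = 0.0163), but adjusted p = 0.607 with an estimated correlation. By the rotation test fry, which asks whether a list's genes move one way on balance and compares them with no other genes, the adjusted p was 0.0801.

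Genes of the TGF-beta response were higher as a list, with most members not passing by themselves. Of 29 measured, 10 rose and 2 fell (11 and 2 adjusted over the list alone), and 6 and 1 of these kept their calls without any single array. Smad3, a signal transducer of the pathway (0.81 ± 0.075), Id1 (0.72 ± 0.071), the receptor gene Tgfbr2 (0.50 ± 0.062) and the inhibitor Smad7 (0.46 ± 0.063) rose. The genes that fell, named after their values were seen, were Bhlhe40 (-0.43) and Id3 (-0.36). Id3 did not pass without control replicate 2 (adjusted p = 0.062), butyrate replicate 1 (0.123) or butyrate replicate 2 (0.0987). The list median was 0.15 (camera, adjusted p = 0.0242), with adjusted p = 0.607 with an estimated correlation, 0.0801 by fry and 0.0541 without control replicate 1.

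**Figure D2:**
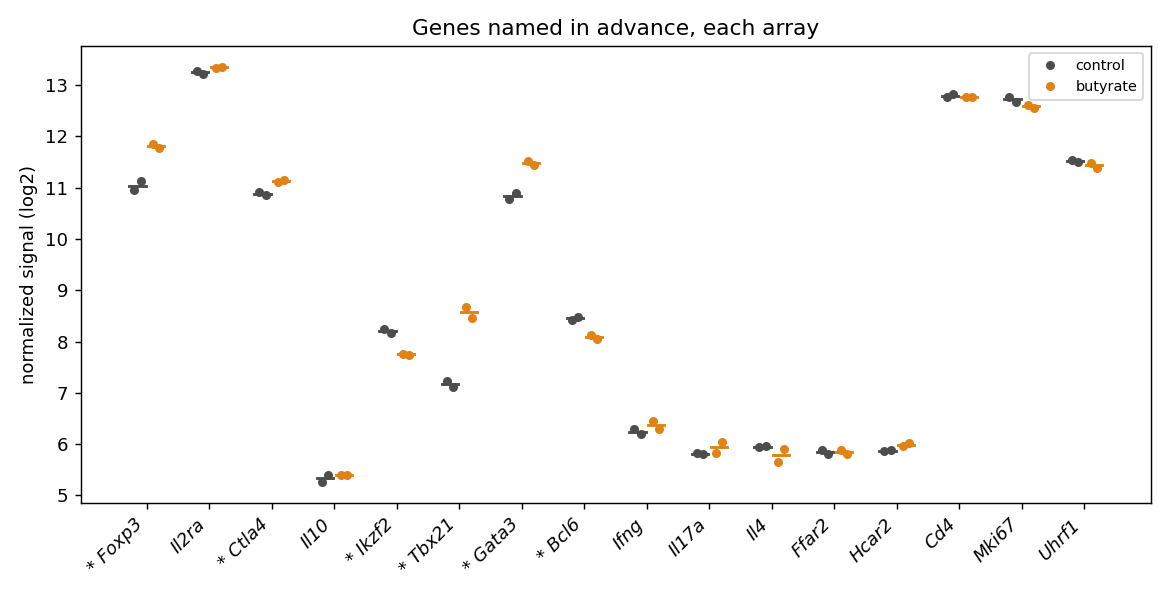
Normalized log2 signal of 16 genes chosen before the data were examined, with a point for each control array (grey) and butyrate array (orange) and a bar at each group mean. Stars mark the 6 genes with an adjusted p under 0.05, and the Foxp3 means lie at 11.04 and 11.81.

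Lineage genes of other helper T cells moved in both directions. Tbx21, which encodes T-bet, the Th1 regulator, rose by 1.39 ± 0.086, and its relative Eomes by 0.88 ± 0.076, while the chemokine genes Xcl1 (-1.83 ± 0.070) and Ccl3 (-1.50 ± 0.074) and the receptor gene Il18r1 (-0.84 ± 0.060) fell. In the Th1 list 6 of 18 members rose and 6 fell (7 and 6 adjusted over the list alone), with a median of 0.04, a mean of -0.11 and no shift as a list (camera, towards lower, adjusted p = 0.733). Ifng differed by 0.13 ± 0.076 (adjusted p = 0.324). Gata3, the Th2 regulator, rose by 0.65 ± 0.069 and Epas1 by 0.65 ± 0.068, and Il9, a cytokine gene, fell by 0.77 on the log2 scale, with an SE of 0.091. The Th2 list had 4 of 19 members higher and 2 lower (5 and 3 adjusted over the list alone), a median of 0.00 that was -0.02 with arrays centred on their median and 0.01 after cyclic loess normalization, and adjusted p = 0.606. The other called members were Il4ra, Irf4 and Il24, which did not pass when either butyrate array was left out (adjusted p from 0.0579 to 0.151), nor, for Il4ra (0.103) and Il24 (0.0816), without control replicate 1. Il4 differed by -0.16 ± 0.084 (adjusted p = 0.266) at a dim signal of 5.95 in controls.

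Th17 genes were lower as a list. Ccr6, a chemokine receptor of Th17 cells (-1.45 ± 0.063), Ahr, the aryl hydrocarbon receptor (-0.88 ± 0.067), and Cxcr6 (-0.61 ± 0.058) fell, and the receptor chain Il6ra rose (0.63 ± 0.066). Of 17 measured, 7 fell and 3 rose (7 and 3 adjusted over the list alone), and 5 and 2 of these kept their calls without any single array. The other rises were Il6st and Stat3, and Stat3 did not pass without butyrate replicate 1 (adjusted p = 0.0824) or butyrate replicate 2 (0.0509). Il17a differed by 0.13 ± 0.079 (adjusted p = 0.375) at a dim signal of 5.81 in controls. The Th17 list had a median of -0.10 (camera, adjusted p = 0.0272), with adjusted p = 0.607 with an estimated correlation. It was 0.0571 without butyrate replicate 1 and 0.149 among genes brighter than the median probe set. Among 15 follicular helper genes 6 fell and Cxcr5 alone rose (6 and 4 adjusted over the list alone). Cd200 (-0.88 ± 0.070), Tox (-0.62 ± 0.065), Pdcd1, which encodes PD-1 (-0.59 ± 0.065), and the regulator Bcl6 (-0.36 ± 0.062) were lower, although Bcl6 did not pass without butyrate replicate 2 (adjusted p = 0.0654). As a list they were not shifted (median 0.00, mean -0.04, towards lower, adjusted p = 0.328).

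Genes of naive and resting T cells were higher as a list. Il7r and the transcription factor Klf2 (1.06 ± 0.089), and its target S1pr1, the receptor that guides exit from lymphoid tissue (1.99-fold), rose. So did the chromatin organizer Satb1 (0.49 ± 0.060). In this list 12 of 27 members rose and 2, Slfn2 (-0.44) and Id3, fell (15 and 3 adjusted over the list alone). When any 1 array was left out 8 rises and the fall of Slfn2 remained, and Id3 had an adjusted p of up to 0.123. The median was 0.23 (camera, adjusted p = 2.6e-05), with adjusted p = 0.607 with an estimated correlation and 0.0777 by fry. Cytokine receptors and their signalling genes were also higher as a list. Il7r, Il10ra and Il6ra had the smallest p among its rises. In all, 14 of 27 were raised and 4 lowered (16 and 4 adjusted over the list alone). Of these, 9 rises and 2 falls kept their calls without any single array. Il18r1 and Jak2 (-0.55) fell, and so did Il15ra and Il12rb1, which did not pass without butyrate replicate 2 (adjusted p = 0.0933 and 0.112), nor Il15ra without control replicate 1 (0.0542) or butyrate replicate 1 (0.0993). The median was 0.24 (camera, adjusted p = 6.62e-05), with adjusted p = 0.607 with an estimated correlation and 0.0603 by fry.

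Activation genes showed no common direction. The nuclear receptor Nr4a2 (-1.53 ± 0.075) and Il2, the gene for interleukin-2 (-0.89 ± 0.067), fell, while Lif (1.43 ± 0.074) and Ier3 (0.86 ± 0.068) rose. Of 34 measured, 10 rose and 6 fell (11 and 9 adjusted over the list alone), of which 4 and 5 kept their calls without any single array (median 0.06, adjusted p = 0.569). Among 27 genes of chemokine receptors and homing, Cxcr5, S1pr1, Gpr183, an oxysterol receptor (0.75 ± 0.059), Itga4 and Ccr8 rose, and Ccr6, Cxcr6 and Itgb1 fell (7 and 3 adjusted over the list alone). Itgb1 did not pass without butyrate replicate 2 (adjusted p = 0.0528), and the list was not shifted (5 higher, 3 lower, median 0.06, adjusted p = 0.364). In the list of 17 cytotoxic genes 4 rose and 2 fell (5 and 3 adjusted over the list alone). Gzmb, a granzyme gene (0.60 ± 0.067), Fasl (0.48 ± 0.060) and Nkg7 (0.44 ± 0.059) rose and Serpinb9, a granzyme B inhibitor gene, fell (-0.86 ± 0.069). Ctsw rose and Serpinb6b fell, but without butyrate replicate 2 neither passed (adjusted p = 0.0855 and 0.0956), nor did Serpinb6b without butyrate replicate 1 (0.0564). The cytotoxic median was 0.07 (camera, adjusted p = 0.364, and 0.0362 by fry).

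Mitotic genes were lower with butyrate, and genes of DNA replication were not shifted. Of 44 mitosis genes measured, 34 fell and 1, the securin gene Pttg1 (0.49), rose (35 and 1 adjusted over the list alone). The kinesin Kif4 (-0.61 ± 0.068), the kinetochore gene Cenpf (-0.65 ± 0.077), Cdc20, an activator of the anaphase-promoting complex (-0.58 ± 0.061), and Hmmr (-0.51 ± 0.058) were examples. The list median was -0.35 (camera, adjusted p = 1.19e-20), with adjusted p = 0.257 with an estimated correlation. Without any single array 12 of the falls kept their calls, and the list kept its call in each of those fits. The proliferation marker Mki67, a member, differed by -0.14 ± 0.065 (adjusted p = 0.234). In the DNA replication and S phase list, also of 44 genes, the median was -0.04 (adjusted p = 0.364). The called members were E2f1, which rose (0.32), and E2f8 (-0.32), Tyms (-0.29) and Mcm10 (-0.22), which fell (1 and 2 adjusted over the list alone). None of these 4 passed without butyrate replicate 2 (adjusted p from 0.0528 to 0.237). E2f1, Tyms and Mcm10 were also lost without butyrate replicate 1 (0.0626 to 0.134), E2f8 and Mcm10 without control replicate 2 (0.0788 and 0.0985), and Mcm10 without control replicate 1 (0.0948). Uhrf1 differed by -0.08 ± 0.063 (adjusted p = 0.469).

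Inhibitors of cyclin-dependent kinases and p53 targets were split, with 9 of 24 lower and 6 higher (13 and 6 adjusted over the list alone), and 4 and 4 of these held without any single array. Plk2 (-1.53 ± 0.070), Sesn2 (-1.40 ± 0.060) and Perp (-1.11 ± 0.091), all p53 targets, fell, and Gadd45g rose. Cdkn1a was not analysed here because no probe set names it alone. The median was -0.21 (camera, adjusted p = 0.0257), with adjusted p = 0.607 with an estimated correlation. That call was lost without butyrate replicate 1 (adjusted p = 0.0752) and among genes brighter than the median probe set (0.217). Apoptosis genes were not shifted (24 measured, median -0.02, adjusted p = 0.733). In that list Fasl rose, the death receptor gene Tnfrsf10b fell (-0.43 ± 0.063), and Bmf and Bid rose while Tnfsf10, Bbc3 and Bcl2l1 fell (5 higher and 7 lower adjusted over the list alone, against 3 and 4 over all genes). Bmf (adjusted p = 0.0513) and Bbc3 (0.122) did not pass without butyrate replicate 1, nor Bid (0.109) and Tnfsf10 (0.133) without butyrate replicate 2. Bcl2l1 was lost without control replicate 1 (0.109) and without either butyrate array (0.101 and 0.177).

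Genes of endoplasmic reticulum stress and of ATF4, the transcription factor of the amino acid response, were lower as a list. Slc7a3 (-2.14 ± 0.070), Slc7a11 (-1.83 ± 0.076), the asparagine synthetase gene Asns (-1.60 ± 0.061) and Sesn2 (-1.40 ± 0.060) fell. Of the 31 measured, 17 fell and 1, Xbp1 (0.34), rose (18 and 1 adjusted over the list alone). Of the falls, 10 kept their calls without any single array, and Xbp1 did not pass without butyrate replicate 1 (adjusted p = 0.0606) or butyrate replicate 2 (0.0588). The median was -0.28 (camera, adjusted p = 3.28e-11), with adjusted p = 0.34 with an estimated correlation. Heat shock and oxidative stress genes mostly did not pass, with 3 of 23 lower and 0 higher by limma (5 and 0 adjusted over the list alone, 7 and 1 at an unadjusted p under 0.05, median -0.02, adjusted p = 0.108), and the sign of the median turned after cyclic loess normalization (0.01). Slc7a11 was one of these. For Hspd1, another of them, a second probe set outside the comparison changed by -0.33 (limma over probe sets, adjusted p = 0.0178), against -0.22 for the tested one. Hmox1 (-0.25) and Hspd1 (-0.22) did not pass without control replicate 2 (adjusted p = 0.0921 and 0.141) or either butyrate array (0.14 to 0.208), nor Hspd1 without control replicate 1 (0.0598).

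Ribosome biogenesis genes were slightly lower as a list, with 6 of 32 lower and 0 higher by limma (15 and 0 adjusted over the list alone, 19 and 0 at an unadjusted p under 0.05). Utp20 (-0.45 ± 0.064), a component of the small-subunit processome, kept its call when any 1 array was left out. Gar1 (-0.31), Dkc1 (-0.29) and Nop14 (-0.30) did not pass without butyrate replicate 2 (adjusted p from 0.0666 to 0.173). Dkc1 and Gar1 were also lost without butyrate replicate 1 (0.0924 and 0.0856), and Dkc1 and Nop14 without control replicate 2 (0.0705 and 0.0572). The median was -0.18 (camera, adjusted p = 2.52e-07), with adjusted p = 0.428 with an estimated correlation. Cytosolic ribosomal proteins had 0 of 23 members called by limma (0 adjusted over the list alone and 0 at an unadjusted p under 0.05), with a median of 0.04 (adjusted p = 0.413) and Rpl7 at 0.12 ± 0.066 (adjusted p = 0.307).

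For oxidative phosphorylation 1 of 35 genes rose, Uqcrfs1 (0.30), and 1 fell, Uqcrc1 (-0.36), with the same counts adjusted over the list alone and a median of -0.04 (adjusted p = 0.0923, and 0.0297 without butyrate replicate 2). Without butyrate replicate 2 neither gene passed (adjusted p = 0.102 and 0.0789), nor did Uqcrfs1 without control replicate 2 (0.0696) or butyrate replicate 1 (0.116). The mitochondrially encoded list had 1 measured member, COX2 (0.10 ± 0.089, adjusted p = 0.549 by limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05), too few for a list test. In the glycolysis list of 22 genes 6 rose and 3 fell (6 and 4 adjusted over the list alone). Aldoc, an aldolase (1.05 ± 0.062), and Egln3, an oxygen sensor (0.46 ± 0.062), rose, and Vegfa, a growth factor gene that hypoxia induces, fell (-0.65 ± 0.067). The other falls, Slc2a1 and Pfkl, did not pass without butyrate replicate 2 (adjusted p = 0.111 and 0.0903), nor Pfkl without butyrate replicate 1 (0.0688). The glycolysis list was not shifted (median -0.01, mean 0.05, towards lower, adjusted p = 0.99, median 0.01 after cyclic loess normalization).

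In the list of cholesterol and fatty acid synthesis genes 7 of 26 fell and 3 rose (10 and 3 adjusted over the list alone). Idi1 (-0.64 ± 0.058), Insig1 (-0.53 ± 0.065), Msmo1 (-0.41 ± 0.059) and Lss (-0.39 ± 0.059) were among those that fell. Scd1 (0.62), Scd2 (0.31) and Fads2 (0.24), which encode desaturases, rose, and the desaturase gene Fads1 did not pass (-0.10, adjusted p = 0.336). Scd2 and Fads2 did not pass without either butyrate array (adjusted p from 0.0613 to 0.188), nor Fads2 without control replicate 1 (0.103) or control replicate 2 (0.0614). The list median was -0.09 (camera, adjusted p = 0.0242), with adjusted p = 0.607 with an estimated correlation. That call was lost without control replicate 2 (adjusted p = 0.0609) and without butyrate replicate 2 (0.0538). It was also lost with quantile normalization (0.0693), after cyclic loess normalization (0.153) and among the brighter genes (0.155). Fry gave 0.0801. In fatty acid beta-oxidation, Cpt1a, which controls entry of fatty acids into mitochondria, rose (0.58 ± 0.080) and Acsl5 fell (-0.47 ± 0.060). The list had 4 of 26 members higher and 4 lower (4 and 4 adjusted over the list alone, median 0.06, adjusted p = 0.456). Its other calls, Acadvl, Acads and Acaa2 upward and Oxct1, Echs1 and Acot2 downward, did not pass without butyrate replicate 2 (adjusted p from 0.0533 to 0.261). Apart from Acot2 they were also lost without butyrate replicate 1 (0.0608 to 0.149), Acot2, Echs1 and Acaa2 without control replicate 2 (0.0658 to 0.125), and Acads and Acaa2 without control replicate 1 (0.074 and 0.052).

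Short-chain fatty acid genes included 5 rises and 1 fall among 17 measured (5 and 2 adjusted over the list alone). The monocarboxylate transporters Slc16a7 (0.70 ± 0.091) and Slc16a3 (0.48 ± 0.071) and the acetyl-CoA synthetase Acss1 (0.49 ± 0.069) rose. Slc16a7 was dim, at 5.18 in controls and 5.88 with butyrate. Acss2 (0.48) and Abcg2 (0.35) rose but did not pass without butyrate replicate 1 (adjusted p = 0.137 and 0.0625), and Slc16a1, which fell (-0.22), was lost without each array in turn (0.0856 to 0.177). The receptor genes Ffar2 (0.00 ± 0.064, adjusted p = 0.992) and Hcar2 (0.12 ± 0.060, adjusted p = 0.261) showed no detectable change at dim signals of 5.85 and 5.87 in controls. The list median was 0.06 (adjusted p = 0.0923, and 0.0482 without control replicate 2).

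Genes known to rise with histone deacetylase inhibitors in other cells were higher as a list. Of 28 measured, 8 rose and 1, Alpl (-0.56 ± 0.066), fell (8 and 1 adjusted over the list alone), of which 3 and 1 kept their calls without any single array. Gsn, the gelsolin gene (1.39 ± 0.072), Ctsl (0.57 ± 0.076) and Gadd45b (0.43 ± 0.060) rose. H1f0 was not analysed here, since no probe set names it alone. The median was 0.10 (camera, adjusted p = 0.0257), with adjusted p = 0.607 with an estimated correlation. That call was lost without control replicate 1 (adjusted p = 0.0784), without butyrate replicate 2 (0.0538) and among the brighter genes (0.0508), and fry gave 0.0801. Among 30 histone deacetylases and acetyltransferases, Hdac1 (0.36), Hdac5 (0.34) and Hdac11 (0.32) rose and Sirt1 (-0.39), Kat5 (-0.23) and Kat2b (-0.22) fell (4 and 4 adjusted over the list alone). Each of these 6 lost its call when some 1 array was left out. Hdac1 and Sirt1 did so without butyrate replicate 2 (adjusted p = 0.0585 for each), Hdac5 without butyrate replicate 1 (0.0998), and Hdac11 without control replicate 1 (0.0801) or either butyrate array (0.052 and 0.162). Kat5 and Kat2b did so without each array (0.0734 to 0.22). The list was not shifted (3 higher, 3 lower, median -0.01, mean 0.01, towards lower, adjusted p = 0.978). Its median was 0.02 with quantile and 0.03 after cyclic loess normalization.

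DNA methylation genes had 2 falls among 13, Tet2 (-0.27) and Mbd3 (-0.24), and 0 rises by limma (2 and 0 adjusted over the list alone, 3 and 0 at an unadjusted p under 0.05, median 0.01, mean -0.05, towards lower, adjusted p = 0.379, median -0.01 with arrays centred on their median and after cyclic loess normalization). Both genes were lost without control replicate 1 (adjusted p = 0.0877 and 0.0582), butyrate replicate 1 (0.0715 and 0.129) and butyrate replicate 2 (0.176 and 0.19), and Mbd3 without control replicate 2 (0.103). For 18 histone genes the median was -0.01 and the mean 0.02 (towards lower, adjusted p = 0.998), with 2 higher and 1 lower (2 and 1 adjusted over the list alone). H1f1, a linker histone gene, rose (0.45 ± 0.070). H1f10 rose (0.27) and H2ac4 fell (-0.32), but neither passed without butyrate replicate 1 (adjusted p = 0.14 and 0.151) or butyrate replicate 2 (0.172 and 0.134), nor H1f10 without control replicate 1 (0.145) or H2ac4 without control replicate 2 (0.103).

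Interferon response genes were higher as a list. An exception was Ifih1, the MDA5 sensor gene, which fell by 1.81 on the log2 scale, with an SE of 0.083. Usp18 (0.89 ± 0.074) and the immunoproteasome genes Psmb8 (0.58 ± 0.067) and Psmb9 (0.40 ± 0.059) rose. In all 10 of 29 rose and 1 fell (14 and 1 adjusted over the list alone), of which 5 and 1 kept their calls without any single array. The median was 0.19 (camera, adjusted p = 7.76e-05), with adjusted p = 0.428 with an estimated correlation.

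T cell identity genes did not shift together (20 measured, 5 higher, 3 lower, 6 and 5 adjusted over the list alone, median 0.01, adjusted p = 0.733, median -0.01 with arrays centred on their median). Cd4 differed by -0.03 ± 0.060 (adjusted p = 0.823). Cd7 (0.72 ± 0.067) and Gata3 rose, and Cd96 (-0.49 ± 0.061), Cd5 (-0.42 ± 0.063) and Cd6 (-0.39) fell. Cd2, Skap1 and Cd247 rose but did not pass without butyrate replicate 2 (adjusted p from 0.0527 to 0.0817). Of 20 B cell markers 2 rose and 0 fell by limma (2 and 0 adjusted over the list alone, 5 and 0 at an unadjusted p under 0.05, median 0.04, adjusted p = 0.159). Both encode parts of class II antigen presentation, H2-Ab1 (1.26 ± 0.060) and Cd74 (0.49 ± 0.069), while H2-Aa (0.18 ± 0.064, adjusted p = 0.115) and Cd79b (0.18 ± 0.077, adjusted p = 0.178) did not pass. The H2-Aa signal was dim, at 4.79 in controls. Of 24 myeloid and dendritic cell markers Cd68 alone was called (0.43 ± 0.064, also the 1 call adjusted over the list alone, median 0.05, adjusted p = 0.364). By limma 0 of 14 neutrophil markers were called (0 adjusted over the list alone, 2 at an unadjusted p under 0.05, median 0.04, adjusted p = 0.39). Among 17 markers of NK and CD8 T cells Eomes (0.88 ± 0.076) and Cd8b1 (0.38 ± 0.066) rose and Crtam (-0.86 ± 0.080) and Cd160 (-0.65 ± 0.072) fell (2 and 3 adjusted over the list alone, median 0.00, mean -0.02, adjusted p = 0.733). Cd8b1 did not pass without butyrate replicate 1 (adjusted p = 0.0607). In the list of 11 erythroid and platelet markers Epor rose (0.45) and Tfrc, the transferrin receptor gene that dividing T cells also express, fell (-0.33). The counts were 1 and 1 adjusted over the list alone (median 0.05, adjusted p = 0.456), and without butyrate replicate 1 neither passed (adjusted p = 0.059 and 0.058), nor did Tfrc without butyrate replicate 2 (0.0623).

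**Figure D3:**
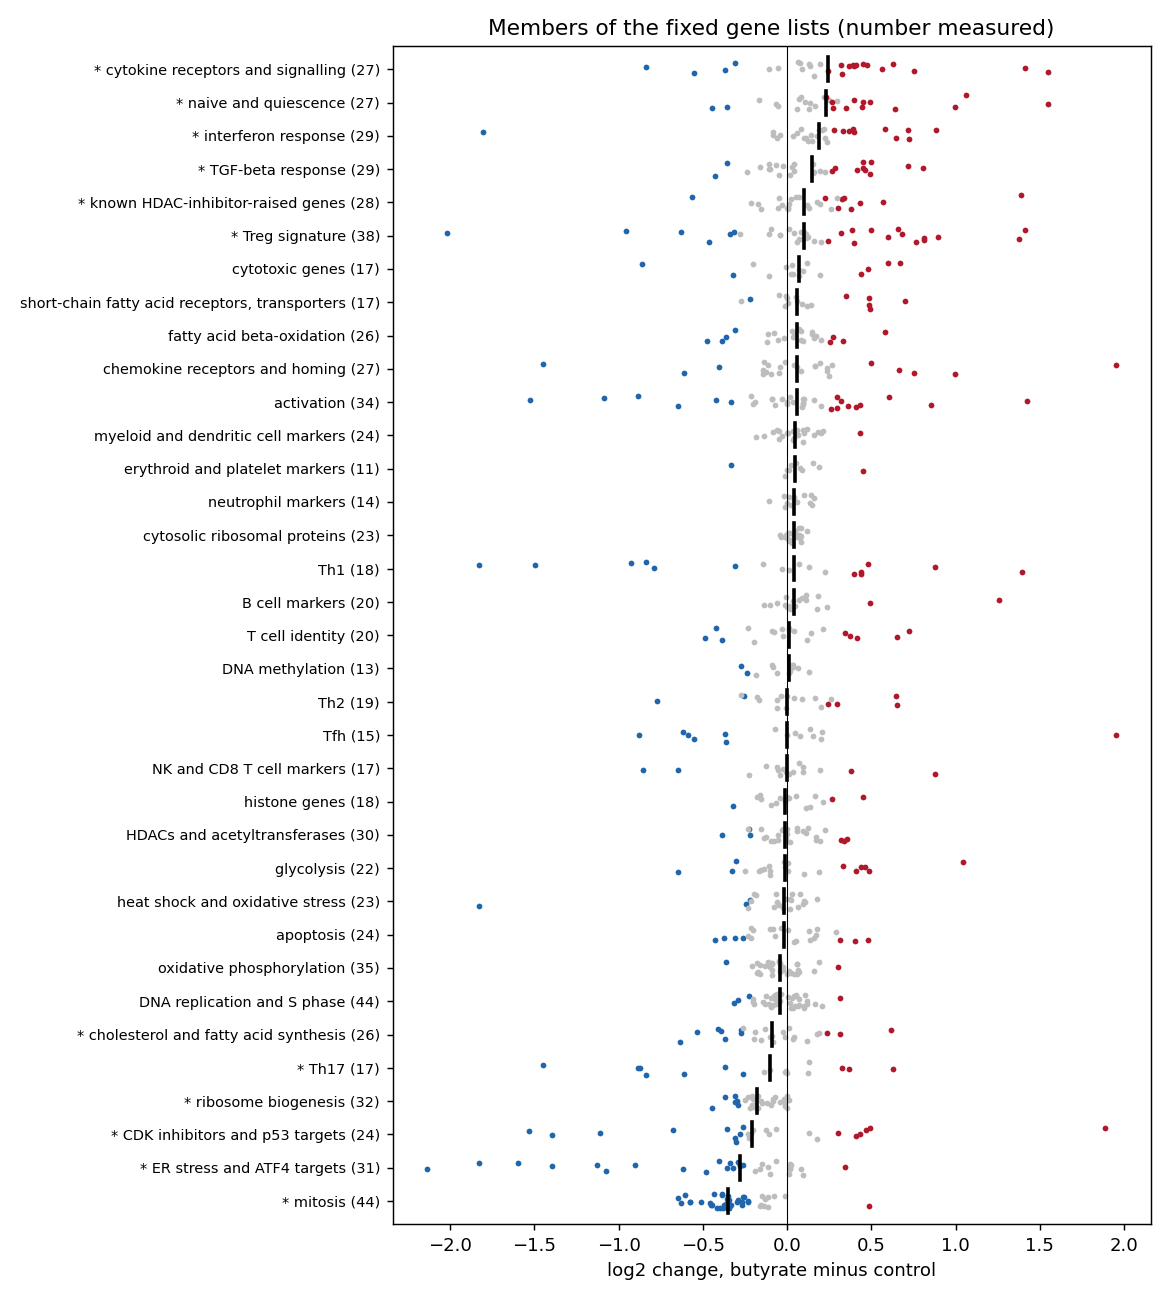
Each line holds one of the 35 gene lists tested, with the number of measured members in brackets. Points are member genes placed by log2 change, butyrate minus control, red where they rose, blue where they fell and grey where they did not pass, with a black bar at the list median and a star at the 12 lists called by camera. Bars run from -0.35 for mitosis to 0.24 for cytokine receptors.

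Of the 35 lists tested, camera called 12, with 6 higher and 6 lower. With an estimated correlation it called 0, with 4 at an unadjusted p under 0.05 and a smallest adjusted p of 0.257. For mitosis, interferon response, and kinase inhibitors and p53 targets the estimate (-0.001, -0.008 and -0.034) lay below the preset 0.01. Yet the unadjusted camera p for mitosis went from 3.4e-22 to 0.0074. Higher correlation thus does not account for those lost calls. With an estimated correlation camera also takes its degrees of freedom from the arrays, not from the genes, and 4 arrays leave few. Fewer degrees of freedom raise p by themselves, so a call lost this way does not by itself show correlation among genes. For others, such as naive and resting genes (0.227), the estimate was higher. Fry called 7, of which 6 were among the 12 and 1, the cytotoxic list, was not.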

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

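Tests of probe sets outside the comparison were made after its result was seen. Among 1621 probe sets paired with several genes, 26 passed limma when tested by themselves, 12 higher and 14 lower with butyrate, with 231 at an unadjusted p under 0.05. Their genes cannot be told from the signal, so no names are given. Of the 12147 probe sets without a listed gene, limma called 0, with 830 at an unadjusted p under 0.05.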

How the results depend on the processing

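Cyclic loess normalization was the one alternative here chosen after the data were seen. The count of 2658 called genes ranged from 1197 (without butyrate replicate 2) to 2777 (without control replicate 2) when any 1 array was left out, with 1323 without butyrate replicate 1. Raised genes ranged from 659 to 1501 and lowered genes from 452 to 1276, and 62.2% of calls were rises without butyrate replicate 2 against 51.6% with all arrays. With a fold change of at least 1.5 there were 437, 257 higher and 180 lower. Testing all probe sets gave 214, 107 higher and 107 lower. Unnamed probe sets scattered more there (median residual SD 0.117 against 0.06), and the prior degrees of freedom were 2.08 in place of 5.92. Quantile normalization kept 1778 of the 2658 calls and left 799 lowered genes, and the cause was not tested. The other settings gave 2286 to 3773 calls. In the refits over all genes 0 of the 2658 called genes were called by limma in the opposite direction, and 2657 kept their sign with the mean of probe sets and 2658 in the others. The filters on signal tested 2355 and 2615 of them, with the same sign. Most of these outcomes were fixed in advance. For all 2658 genes the arrays of the groups did not overlap, so leaving out an array or adding an offset could not turn a sign. The block, variance trend, robust prior and filters leave the difference as it is. Only the normalizations, the centring and the mean of probe sets could have turned it. Of 127 called named genes, 30 lost their call in some refit, thresholds on fold and p apart. Of the 120 that each refit tested, 92 kept it in all. Camera with an estimated correlation called 0 of 35 lists (4 at an unadjusted p under 0.05), and fry 7, of which 6 were among camera's 12, while other settings called 8 to 12. With a replicate block 2641 genes, 12 lists and 124 named genes were called. Arrays with the same number did not deviate together (correlation -0.058), so the numbers are not shown to pair the arrays. Dim signals limit what can be seen, since 33% of probe sets lie below 5.82. Ffar2, Hcar2, Il17a and Il4 lie near that level and Il10 lies below it.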

Other observations

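The gene families and the tests of explanations in this part were all chosen after the results were seen, apart from the lists themselves. Bootstrap intervals in this part run across genes, which are not independent replicates, so they do not measure the spread between arrays. Genes were grouped by symbol stem into 331 families of at least 8 measured genes, and camera called 21, of which 4 were higher and 17 lower. After cyclic loess 16 of the 21 lost their call, and with an estimated correlation camera called 0 families (3 at an unadjusted p under 0.05). Genes of the Gimap family, GTPases of lymphocyte survival, were higher, with 6 of 8 raised and a median of 0.58 (adjusted p = 4.8e-05, and 0.988 with an estimated correlation). Gimap7 rose most, Gimap3 (0.70), Gimap8 (0.70), Gimap4 (0.67), Gimap6 (0.50) and Gimap9 (0.50) rose, and Gimap1 (0.21) and Gimap5 (-0.17) did not pass. Ligands of the tumour necrosis factor family with the stem Tnfsf were lower, with 6 of 9 lowered and a median of -0.38 (adjusted p = 8.61e-05, and 0.988 with an estimated correlation), among them Tnfsf4 (-2.20), Tnfsf8 (-0.70) and Tnfsf14 (-0.63). The stem leaves out ligands of that family with other symbols, of which Fasl (0.48) and Tnf (0.36) rose, so the fall is not one of the whole family. Mitochondrial ribosomal proteins named Mrpl were lower by a small amount (48 genes, 10 lower and 1 higher, median -0.15, adjusted p = 4.8e-05, and 0.988 with an estimated correlation). The direction of these 3 families held under quantile, median and cyclic loess scaling, with adjusted p after cyclic loess of 6.44e-06, 9.32e-05 and 0.0104.

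Mitosis genes were lower by camera (median -0.35, adjusted p = 0.257 with an estimated correlation) while DNA replication genes had a median of -0.04 (95% bootstrap interval -0.07 to 0.03). A normalization effect tied to brightness is argued against, since the mitosis median was -0.31 after cyclic loess and 0 of 10000 lists matched on brightness were as low (lowest -0.12). A smaller share of dividing cells might lower both lists by about as much, though that premise was not tested. Their means differed by -0.29 (permutation p = 1e-05, the smallest that 100000 resamples can give, across genes, which are not independent replicates). That contrast was picked after the values were seen and restates the pattern, so it does not exclude a smaller share of dividing cells. A hypothesis that these tests leave open, and that no value here decides, is that butyrate lowers mitotic transcripts or the share of cells in mitosis without a like change in S phase. A shift in timing of division also stays open and was not tested.

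The list of endoplasmic reticulum stress and ATF4 genes was lower by camera (median -0.28, adjusted p = 0.34 with an estimated correlation). After cyclic loess the median of all 31 genes was -0.25, and 0 of 10000 matched lists were as low (lowest -0.12), which argues against a normalization effect tied to brightness as the whole cause. A general fall of endoplasmic reticulum stress genes would lower the genes of the unfolded protein response too. These 11 genes had a median of 0.02 (bootstrap interval -0.07 to 0.08), with 1 higher and 1 lower. Their signals were not dim (median level 11.6). The 20 others had a median of -0.38 (-0.99 to -0.28). So these 11 genes were not lower as a group. The list was split after its values were seen, so the contrast restates the pattern and does not decide whether endoplasmic reticulum stress genes fell in general. Differences in medium or cell density between cultures stay open and untested.

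Of 8 genes of class II antigen presentation, put together after their values were seen and not tested for enrichment, H2-Ob (1.92), H2-Ab1 (1.26), H2-Oa (0.92), H2-DMa (0.63) and Cd74 (0.49) rose, while H2-Aa (0.18), H2-Eb1 (0.11) and Ciita (0.12) did not pass (median 0.56, 95% bootstrap interval 0.12 to 1.26). H2-Aa (4.79 in controls) and Ciita (6) were dim, so a rise of these could be missed, although H2-Ab1 rose from 6.07. More B cells could raise them, and 8 B cell markers above the dimmest 33% of probe sets had a median of 0.04 (95% bootstrap interval 0.01 to 0.11). That set left out the raised markers H2-Ab1 and Cd74 and kept H2-Eb1, and its signals are dim (median level 6.26), so it excludes nothing. More myeloid or dendritic cells could too, and 11 of their markers, also mostly dim (median level 6.42), had a median of 0.1 (-0.05 to 0.16); a first version over all markers had medians of 0.02 for 16 B cell markers other than class II genes and 0.05 for 24 myeloid markers. The cultures were started from naive CD4+ T cells isolated from spleen, which should leave few other cells, but the labels give no purity, so a rise in the T cells and a few other cells both stay open.

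With 4 arrays there are 3 splits into pairs, too few for a share under 0.05. The real split called 2658 genes and the highest other called 0 by limma (169 and 124 genes at an unadjusted p under 0.05), so only the real split reached its count. In the other splits each group held 1 control and 1 butyrate array. A treatment difference then adds to the spread within groups, so few calls could be made there and the comparison decides nothing.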
